A study of Homo sapiens with 4 samples.

How the data were processed

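Messenger RNA abundance was measured by RNA sequencing in 4 libraries of the human cell line that the labels call J-gammal, 2 controls and 2 labelled as FYB1 knockdown. The source name of the controls says no treatment while their titles carry the letters NC, which the labels do not spell out. Whether the controls were untreated or carried a control construct is not given in the sources used here, so a difference between groups may include an effect of the construct. Per the labels' protocols, RNA was isolated with Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and the genome build was hg38. The counting program, the gene annotation and the use of strand are not given in the sources used here. A number in each sample title, 1 or 2, is used here to name the library within its group. The titles do not say whether the 2 knockdown libraries carry the same construct. Nothing in the labels says that equal numbers mark a shared day or culture, or that the 2 libraries of a group came from separate cultures. P-values therefore measure the spread between these libraries, which may be technical.

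The deposited table holds 1 value per gene and library for 28274 genes, and its header names no unit. The values were identified as FPKM, reads or fragments per kilobase of merged exon relative to a library total, as the authors scaled them. The evidence is that each value times the merged exon length of the gene in GENCODE 29 was a whole multiple of 1 step per library for 100% of genes in each library, within a tolerance of 0.001. All 28274 gene identifiers matched that annotation, and no gene was at 0 in all 4 libraries. Dividing by the step gave whole reads per gene, which sum to 17597678 and 17216663 reads in controls 1 and 2 and to 16693113 and 20251864 in knockdown libraries 1 and 2. The library totals that the authors divided by were 16648943, 16789004, 18436617 and 20480491 in the same order, and they equal the median-of-ratios factors of the recovered reads up to 1 constant (relative sizes of 0.924, 0.932, 1.02 and 1.14 by both routes). A value of 1 FPKM for a gene with 1 kb of exon thus stands for 16.6 to 20.5 reads.

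The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) with a pseudocount of 1, over the 13172 genes with a mean of at least 1 FPKM across the 4 libraries, with the group as the single term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and are given as knockdown minus control with their standard error. The same genes were also tested with limma-voom on the recovered reads, with the authors' totals as library sizes. That test is named wherever its values are given. The main test, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

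Gene lists were tested with camera (preset inter-gene correlation of 0.01, lists with at least 5 tested members), and beside it with camera on an estimated correlation and with fry. The lists were FYB1 partners, T cell receptor complex and T cell surface, T lineage transcription factors, integrins and leukocyte adhesion, actin cytoskeleton, NF-kappaB targets, immediate early genes, cytokines with chemokines and receptors, interferon-stimulated genes, HLA and antigen presentation, DNA replication, mitosis, BCL2 family and apoptosis, p53 targets, ATF4 and amino acid response, endoplasmic reticulum unfolded protein response, heat shock proteins, glycolysis and hypoxia, cholesterol biosynthesis and SREBP targets, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, mitochondrially encoded genes, nuclear oxidative phosphorylation, replication-dependent histones, and markers of myeloid, B, NK and cytotoxic, erythroid and megakaryocyte, stem and progenitor, and epithelial and stromal cells. A list median was also placed among 10000 random lists matched on exon length, GC content and mean expression.

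The named genes are FYB1, the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 5 FPKM and no overlap between groups, up to 4 members of each list past the threshold, and otherwise at most 2 members of a list with the highest mean. The same rule was applied to the recovered-read test after the data had been seen. Other genes named outside the rule are marked where they appear. Alternatives covered a replicate block, quantile normalization, the sum of reads as library total, other filters on low values, pseudocounts of 0.1 and 5, each library left out, a minimum fold of 1.5 and a test against 1.2-fold. A correction that removed a smooth trend on exon length and GC content, a minimum mean of 20 recovered reads and a crossed block were added after the data were seen.

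Words of 7 bases were counted in the 3′ UTR of 1 annotated GENCODE 29 transcript per gene, the one with the longest coding sequence, over 10354 tested protein-coding genes with at least 20 bases of 3′ UTR. The log2 difference was first adjusted for the length and GC content of the UTR, the exon length and GC content of the gene and mean expression. Each of 16265 words found in at least 30 genes then received a z, the mean difference between genes with and without it over its standard error. This scan was added after the data had been seen, and a word planted in shuffled values was recovered as the lowest.

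Both tests were tested on simulated data for the comparison of knockdown with control, with read counts drawn for 13154 genes, 50 of them changed at each of 4 fold sizes. The main test recovered 22% of 1.5-fold, 88% of 2-fold and 100% of 3-fold and 4-fold changes, and called 25 of 12923 unchanged genes. The test on recovered reads found 66%, 96%, 100% and 100%, and called 10 unchanged genes. The genes changed at these fold sizes had a mean of at least 5 FPKM. Counts were drawn independently per gene with a fixed dispersion of 0.01 and no trend with length or GC content. The real libraries held such a trend, so these shares need not hold for them. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.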

Results

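RNA abundance was compared between 2 control libraries and 2 FYB1 knockdown libraries of the J-gammal human cell line. Transcripts of T cells were abundant in the controls. LEF1, a transcription factor of T cell development, averaged 204 ± 6.74 FPKM (SD, n = 2), TRAC, the constant region of the T cell receptor alpha chain, 386 ± 18.9 FPKM, and CD3D, a subunit of the receptor complex, 449 ± 41.9 FPKM. The 4 libraries held 16693113 to 20251864 recovered reads, and the 10 most abundant genes took 6.31% to 6.83% of them. Mitochondrially encoded genes took 4.09% and 4.03% of reads in the controls and 4.92% and 5.14% in the knockdown libraries.

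FYB1 encodes an adaptor protein that links the T cell receptor to integrin activation, and it is the gene that the knockdown targets (chromosome 5, 39105255 to 39274528, minus strand, hg38). It stood at 17.6 and 20.1 FPKM in controls 1 and 2 and at 6.18 and 4.53 FPKM in knockdown libraries 1 and 2, from 2591, 2981, 1009 and 821 reads. The knockdown mean was 0.285 of the control mean. The log2 fold change was -1.65 ± 0.15 (SE), with an adjusted p of 0.0398 by limma-trend, and -1.83 ± 0.15 with an adjusted p of 0.000419 by limma-voom on recovered reads. The call of the main test ended without knockdown library 1 (adjusted p = 0.203), without knockdown library 2 (adjusted p = 0.0555), with every gene above 0 in the test (adjusted p = 0.264) and when tested against 1.2-fold, and the fold change lay between -1.84 and -1.46 without any 1 library.

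The first question was which transcripts differed between the controls and the cells with lowered FYB1. In the knockdown libraries 27 genes passed the threshold, of which 9 rose and 18 fell, and 16 of the 27 were protein coding. TRIB2, a pseudokinase that binds ubiquitin ligases, rose from 56.3 ± 0.64 to 140.4 ± 1.74 FPKM (SD, n = 2 each; 2.49 times the control mean). ZBTB7B, a transcription factor that directs the CD4 T cell lineage, rose from 2.30 ± 0.08 to 8.02 ± 1.3 FPKM (log2 fold change 1.44 ± 0.13). Among the protein-coding genes past the threshold the largest fall was that of ACOT7, an acyl-CoA thioesterase, from 39.1 ± 2.5 to 6.66 ± 1.46 FPKM (log2 fold change -2.40 ± 0.15). RPN2, a subunit of the oligosaccharyltransferase that attaches N-glycans to proteins, fell from 84.9 ± 0.97 to 31.7 ± 2.34 FPKM (log2 fold change -1.40 ± 0.12).

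The other coding genes that fell belong to several cellular systems. GZMM, a granzyme of cytotoxic cells, went from 12.4 to 4.62 FPKM, and STAT5A, a transcription factor downstream of cytokine receptors, from 17.2 to 7.96 FPKM. BPNT1, a nucleotidase of sulfate metabolism, went from 19.0 to 7.46 FPKM. MOCS1, an enzyme of molybdenum cofactor synthesis, went from 32.3 to 13.6 FPKM, and TIMM17A, a subunit of the import channel of the inner mitochondrial membrane, from 15.8 to 6.46 FPKM. PRKAR2A, a regulatory subunit of protein kinase A, went from 9.02 to 3.54 FPKM, and DACT3, a regulator of Wnt signalling, from 7.97 to 2.65 FPKM. GAGE2A, a cancer/testis antigen, went from 43.4 to 15.1 FPKM, and its reads are uncertain because the GAGE genes are nearly identical. NARS, the asparaginyl-tRNA synthetase, ETV5, an ETS transcription factor, and GFRA1, a receptor for GDNF, also fell, and they are named here after their values were seen, to complete the coding genes. They went from 41.9 to 19.2, from 12.9 to 5.90 and from 14 to 6.55 FPKM.

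The other genes past the threshold, noncoding genes and segments of immune receptor genes, mostly rested on few reads. AC002454.1, an antisense gene, fell from 7.76 to 2.48 FPKM, and RPL10AP6, a ribosomal protein pseudogene, from 9.04 to 3.42 FPKM. AL049840.5, a gene inside an intron of another gene, rose from 3.03 to 9.45 FPKM. These 3 loci overlap or resemble other genes, and without a stated use of strand their reads cannot be assigned with certainty. MIR8078 had 4, 4, 11 and 15 reads in controls 1 and 2 and knockdown libraries 1 and 2, and IGHD6-6, an immunoglobulin diversity segment, 0, 0, 5 and 3. In all, 7 of the 27 genes had under 20 reads in every library, and 1 of these 7 was also called on recovered reads.

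**Figure D1:**
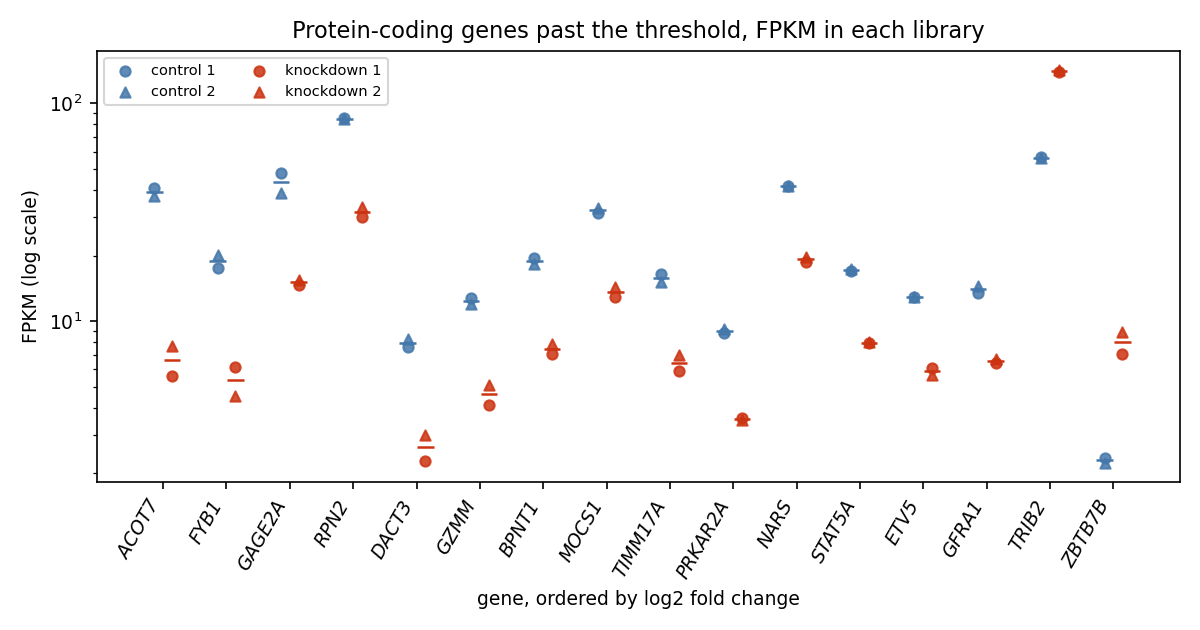
FPKM on a log scale (y axis) of the 16 protein-coding genes past the threshold (x axis, ordered by log2 fold change) in each control (blue) and knockdown (red) library, with short lines at the group means. Both knockdown libraries lie below both controls for the 14 genes that fell, from ACOT7 to GFRA1, and above them for TRIB2 and ZBTB7B.

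The smallest adjusted p over all genes was 0.0398, although 3088 genes had an unadjusted p under 0.05 by limma-trend. Limma-voom on recovered reads called 1019 genes, 255 higher and 764 lower, and these included 21 of the 27. The main count was 0 without knockdown library 1 and 0 without knockdown library 2, where 2205 and 4841 genes had an unadjusted p under 0.05, and 228 and 406 without control 1 and control 2.

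Of the 13 coding genes other than FYB1 that fell, 9 carried the 7-base word TCACAGT in the coding sequence or the 3′ UTR. They were ACOT7, RPN2, MOCS1, TIMM17A, BPNT1 and PRKAR2A with the word in the 3′ UTR, NARS with it in both parts, and STAT5A and GAGE2A with it in the coding sequence. Of the 10340 other coding genes, 23.1% carried it (two-sided Fisher's exact test, p = 0.000527). From genes of similar length 2.23 carriers were expected. FYB1 itself carries the word once, in the coding part of exon 2 of 19 (chromosome 5, 39202538 to 39202544, minus strand, hg38). Neither TRIB2 nor ZBTB7B carries it. The word was found in the same libraries, in a scan of all 7-base words, so the test is not independent of the values. On recovered reads the 712 coding genes that fell were not richer in carriers (20.8% against 23.3%, two-sided Fisher's exact test, p = 0.129), and the 217 that rose were (33.6% against 22.9%, p = 0.00043 by the same exact test). These shares on recovered reads were not matched on length. Longer coding genes can hold more words and were higher in the knockdown libraries (Spearman correlation of 0.45 with exon length), so the shares do not isolate the word.

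**Figure D2:**
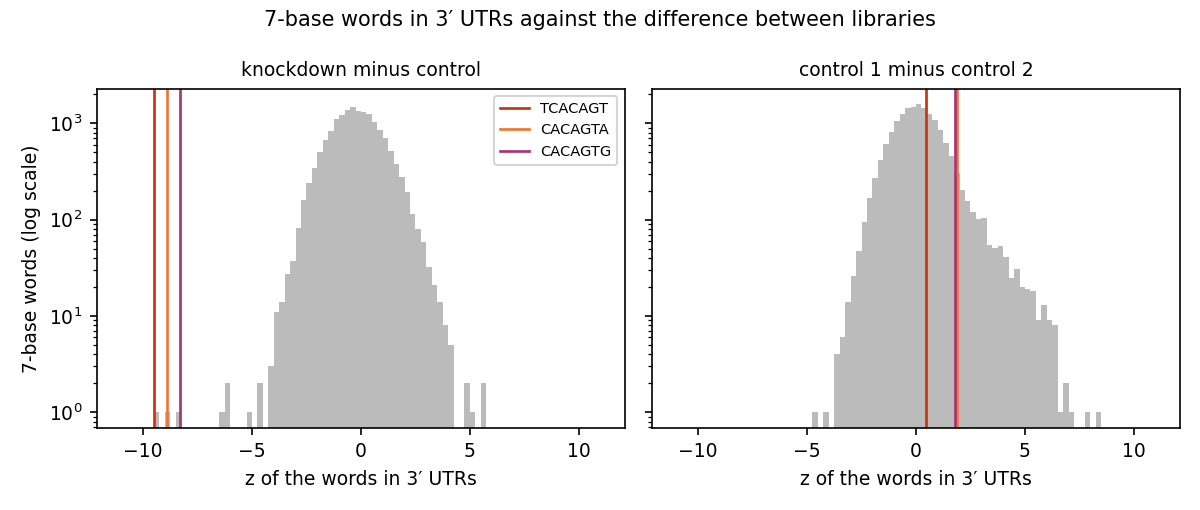
Number of 7-base words (y axis, log scale) by their z in 3′ UTRs after adjustment for length, GC content and expression (x axis) for knockdown minus control (left) and control 1 minus control 2 (right), with coloured lines at 3 words that share CACAGT. TCACAGT is the lowest of 16265 words on the left at -9.48, and on the right it lies at 0.44.

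A second question was which groups of genes moved together. Of 27 lists with at least 5 tested members, camera called 12, 10 lower and 2 higher in the knockdown libraries. None was called with an estimated correlation (lowest adjusted p = 0.737 with an estimated correlation, and 0 of 27 with an unadjusted p under 0.05). That version has little power with 2 libraries per group, so it does not decide whether members of a list vary together. Fry called none in a common direction (lowest adjusted p = 0.294). Its mixed test, for changes in either direction, passed some lists, with immediate early genes and cytokines lowest (fry mixed adjusted p = 0.00582 for each). It did not pass glycolysis (fry mixed adjusted p = 0.083) and does not compare a list with other genes. The library totals set the zero of these values. With the sum of reads in place of the authors' totals the median log2 fold change of all genes moved from -0.03 to 0.08.

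Genes of sugar metabolism and the oxygen response were lower in the knockdown libraries. All 32 tested members of the glycolysis and hypoxia list had lower means (median log2 fold change -0.43, camera adjusted p = 4.36e-07, and adjusted p = 0.737 with an estimated correlation). The median was -0.20 under quantile normalization and -0.29 with the sum of reads as library total, both still called. The main test called 0 members over all genes and 7, all lower, adjusted over the list alone, and limma-voom on recovered reads called 11, all lower. Among these 11, SLC2A1, the glucose transporter GLUT1, fell from 52.0 ± 2.66 to 24.6 ± 5.37 FPKM (limma-voom adjusted p = 0.00428). PFKFB4, a regulator of fructose 2,6-bisphosphate, fell from 35.0 to 20.1 FPKM, HK1, a hexokinase, from 55.0 to 34.8 FPKM, and ADM, the hormone adrenomedullin, from 4.93 to 2.35 FPKM.

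Chaperones of the endoplasmic reticulum showed the same direction. The unfolded protein response list had 20 of 24 members lower (median -0.31, camera adjusted p = 0.000321, and adjusted p = 0.737 with an estimated correlation). Its median was -0.21 under quantile normalization and -0.19 with the sum of reads as library total, both still called. Adjusted over the list alone, the main test called 12 members lower and 2 higher, and over all genes 0. By limma-voom 10 fell and 1 rose. CALR, the chaperone calreticulin, fell from 691 ± 24.1 to 306 ± 47.0 FPKM, HSPA5, the chaperone BiP, from 128 ± 11.9 to 66.4 ± 4.39 FPKM, SDF2L1 from 65.8 to 32.7 FPKM and XBP1, a transcription factor of this response, from 56.0 to 31.4 FPKM (limma-voom adjusted p = 0.00428, 0.0049, 0.0115 and 0.00943). The heat shock protein list was lower as well (median -0.44, 16 of 17 members lower, adjusted p = 0.000553, and 0.737 as the adjusted p with an estimated correlation; 5 members lower adjusted over the list alone and 0 over all genes). The heat shock median was -0.14 under quantile normalization and -0.28 after the length and GC correction. DNAJB1, a cochaperone of HSP70, fell from 65.4 to 32.8 FPKM by limma-voom, and HSPA1B, whose reads are uncertain because HSPA1A is nearly identical, from 3.4 to 1.13 FPKM.

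Lists of biosynthesis and amino acid supply were also lower by camera. Cholesterol biosynthesis and SREBP targets had 27 of 28 members lower (median -0.28, adjusted p = 0.000192, and 0.737 with an estimated correlation), and by limma-voom 5 fell, among them FDFT1, the squalene synthase, from 128 to 76.5 FPKM and SCD, a fatty acid desaturase, from 191 to 128 FPKM. The ATF4 and amino acid response list had 21 of 27 members lower (median -0.30, adjusted p = 0.00276, and 0.737 with an estimated correlation), and by limma-voom 6 fell, among them GARS, the glycyl-tRNA synthetase, from 59.8 to 34.5 FPKM and PSAT1, an enzyme of serine synthesis, from 157 to 92.5 FPKM. Ribosome biogenesis and MYC targets had 25 of 31 members lower (median -0.24, adjusted p = 0.00472, and 0.737 with an estimated correlation). TFRC, the transferrin receptor, fell from 25.5 to 15.9 FPKM by limma-voom. The HLA and antigen presentation list had 13 of 17 members lower (median -0.26, adjusted p = 0.0331, and 0.737 with an estimated correlation). With the sum of reads as library total the medians of cholesterol, ATF4, ribosome biogenesis and HLA were -0.14, -0.19, -0.11 and -0.13, all still called, and with quantile normalization -0.16, -0.09, -0.13 and -0.13. After the length and GC correction the medians of ATF4, ribosome biogenesis and HLA were -0.19, -0.11 and -0.13. Adjusted over the list alone the main test called 6, 5, 1 and 0 members in the same order, all lower, and over all genes 0. Under quantile normalization the lists of heat shock proteins, ATF4, ribosome biogenesis and HLA were no longer called (adjusted p = 0.0639, 0.291, 0.0781 and 0.244), and the calls of ATF4 and HLA also ended without knockdown library 1 (adjusted p = 0.0517 and 0.193). The median of HLA was then -0.12 and that of ribosome biogenesis -0.14, and without control 1 that of HLA was -0.16. The HLA call ended as well with a mean of at least 5 FPKM and after the length and GC correction. In the main test the ATF4 and HLA medians lay at percentiles 4.21 and 6.92 of random lists matched on length, GC content and expression.

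The nuclear and mitochondrial genes of respiration went in opposite directions. Of 41 nuclear oxidative phosphorylation genes 38 were lower (median -0.42, adjusted p = 6.62e-07, and adjusted p = 0.737 with an estimated correlation), and 12 fell by limma-voom, among them COX8A and COX6A1, subunits of cytochrome c oxidase, from 349 to 223 and from 77.1 to 46.6 FPKM, and SDHD, a subunit of succinate dehydrogenase, from 20.2 to 13.3 FPKM. All 15 mitochondrially encoded genes had higher means (median 0.17, adjusted p = 0.00472, and 0.737 with an estimated correlation), with MT-CO2 at 8093 and 9117 FPKM in the control and knockdown means and no member called by either test. All 57 cytosolic ribosomal protein genes had lower means (median -0.43, adjusted p = 9.61e-10, and 0.737 with an estimated correlation), and RPS2, RPS9 and RPL12 fell by limma-voom, RPS2 from 1552 to 901 FPKM. The main test called 0 members of these 3 lists over all genes and 0 adjusted over the list alone. Knockdown library 1 carried much of both falls. Without it the medians were -0.21 for nuclear oxidative phosphorylation and -0.23 for ribosomal proteins, both still called, while control 1 minus control 2 was 0.17 and 0.18. Without knockdown library 2 the ribosomal protein median was -0.65. Under quantile normalization the median was -0.19 for nuclear oxidative phosphorylation, still called, and -0.02 for ribosomal proteins (adjusted p = 0.689). With the sum of reads as library total these medians were -0.28 and -0.29, both called. The mitochondrial median was 0.23 under quantile normalization and 0.31 with the sum of reads, both still called. The mitochondrial call ended without control 2 and without knockdown library 2 (medians of 0.14 and 0.04), and without knockdown library 1 the median was 0.26.

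**Figure D3:**
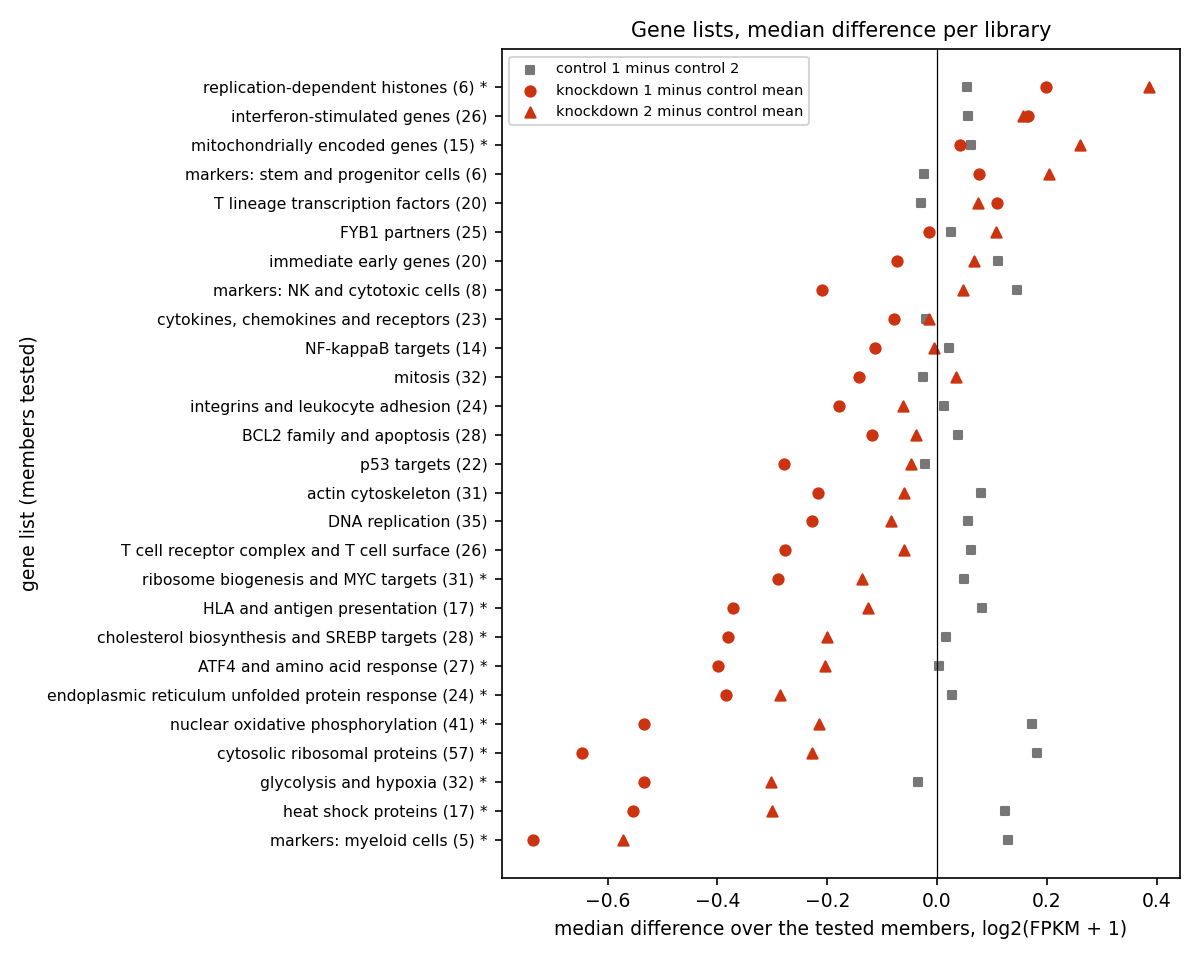
Median difference of log2(FPKM + 1) over the tested members (x axis) of the 27 gene lists (y axis, number of members in parentheses, asterisk where camera's adjusted p was under 0.05), for each knockdown library minus the control mean (red) and control 1 minus control 2 (grey). The glycolysis list lies at -0.53 and -0.30 in knockdown libraries 1 and 2 and at -0.03 between the controls, and the ribosomal protein list at -0.65, -0.23 and 0.18.

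Lists of T cell function did not pass the camera threshold, while some of their members passed the recovered-read test. FYB1 partners had a median of 0.03 over 25 members (adjusted p = 0.0714), with 0 members called by limma-trend or limma-voom and 2 at an unadjusted p under 0.05 by limma-trend. The list was called higher under quantile normalization and with the sum of reads as library total (median 0.18 and 0.16, adjusted p = 0.00199 and 0.00763). It was not called after the length and GC correction (median 0.03, camera adjusted p = 0.125). Its median in the main test lay at percentile 87.3 of random lists matched on length, GC content and expression. VAV1, a guanine nucleotide exchange factor, had means of 51.9 and 52.8 FPKM in control and knockdown, and TLN1, the integrin activator talin, 47.7 and 56.6 FPKM. The T cell receptor and T cell surface list had a median of -0.17 over 26 members (adjusted p = 0.178), with 8 members lower and 2 higher adjusted over the list alone, and 0 called over all genes. Its median was 0.01 under quantile normalization and -0.05 with the sum of reads as library total. Against the control mean it was -0.28 in knockdown library 1 and -0.06 in knockdown library 2. Random lists matched to it on length, GC content and expression had a median of -0.17 as well. After the length and GC correction the list median was -0.02. By limma-voom TRBC1, a constant region of the receptor beta chain, fell from 1320.4 to 558 FPKM, CD3D from 449 to 262 FPKM and CD1A, a lipid-presenting molecule, from 10.8 to 6.41 FPKM, while CD28, a costimulatory receptor, rose from 5.93 to 10.5 FPKM. TRBC1 and TRBC2 are nearly identical, so the reads of each are uncertain. TRAC had means of 386 and 432 FPKM (limma-voom adjusted p = 0.459).

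Several other immune lists held changes in both directions by limma-voom. Among T lineage transcription factors (median 0.10, adjusted p = 0.126, and called higher under quantile normalization with a median of 0.27 and an adjusted p of 0.0371), IKZF3 rose from 1.38 to 2.94 FPKM, and LMO1 and NOTCH3 fell from 5.81 to 2.92 and from 9.83 to 6.90 FPKM by limma-voom. Among integrins and adhesion genes (median -0.07, adjusted p = 0.602), ITGB7 and CCR7 rose from 3.60 to 6.13 and from 4.53 to 7.81 FPKM by limma-voom. Under quantile normalization the integrin median was 0.02. In the actin cytoskeleton list (median -0.11, adjusted p = 0.424, and called higher under quantile normalization with a median of 0.12 and an adjusted p of 0.0151) ACTN1 rose from 11.5 to 17.4 FPKM and ARPC2, of the Arp2/3 complex, fell from 48.2 to 30.3 FPKM by limma-voom. By limma-voom 2 immediate early genes rose and 4 fell (list median 0.02, adjusted p = 0.983), with rises of KLF2 from 28.0 to 56.0 FPKM and EGR1 from 4.51 to 8.95 FPKM and a fall of MYC from 39.9 to 23.0 FPKM. Of the cytokine and receptor list (median -0.04, adjusted p = 0.551) the main test called 1 member, STAT5A. NF-kappaB targets had a median of -0.07 and interferon-stimulated genes of 0.18 (adjusted p = 0.964 and 0.138). By limma-voom no NF-kappaB target was called and 2 interferon-stimulated genes fell, among them IFI6 from 66.0 to 33.3 FPKM.

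Lists of proliferation and cell death did not pass camera. The medians were -0.15 for DNA replication, -0.07 for mitosis, -0.09 for the BCL2 family and apoptosis and -0.09 for p53 targets (adjusted p = 0.168, 0.957, 0.983 and 0.377). Against the control mean they were -0.23, -0.14, -0.12 and -0.28 in knockdown library 1, and -0.08, 0.03, -0.04 and -0.05 in knockdown library 2. Random lists matched on length, GC content and expression had medians of -0.15, -0.10, -0.11 and -0.10 in the same order. PCNA, the sliding clamp of replication, had means of 188 and 157 FPKM, and MCL1, an inhibitor of apoptosis, 47.2 and 48.6 FPKM. By limma-voom RRM2, a subunit of ribonucleotide reductase, rose from 16.3 to 23.8 FPKM and TK1, a thymidine kinase, fell from 46.3 to 31.5 FPKM. BIRC5, the mitotic protein survivin, fell from 51.0 to 32.1 FPKM by the same test. In the BCL2 and apoptosis list, also by limma-voom, BAD fell from 29 to 17.6 FPKM, and CASP8 and TNFRSF10A rose from 9.13 to 12.4 and from 0.84 to 1.76 FPKM. Of the p53 targets MDM2 rose from 4.10 to 7.04 FPKM and PHLDA3 fell from 16.1 to 10.3 FPKM by limma-voom. Replication-dependent histones were higher (median 0.29, 5 of 6 members higher, adjusted p = 0.0338, and adjusted p = 0.737 with an estimated correlation; 3 members adjusted over the list alone and 0 over all genes). That call ended without control 2, without knockdown library 2, with every gene above 0 in the test, under quantile normalization and on recovered reads (adjusted p from 0.0639 to 0.147 in these settings), with medians of 0.23, 0.20, 0.05, 0.29 and 0.36 in the same order. The median and the camera direction differed in sign for mitosis, immediate early genes and the cytokine list, none of which was called, and the median and mean for stem and progenitor markers (0.13 and -0.02). Under quantile normalization the medians of DNA replication, mitosis and the BCL2 family turned positive (0.02, 0.15 and 0.03), and mitosis was then called higher (adjusted p = 0.021). With the sum of reads as library total the medians of 8 lists that were negative and not called turned positive without a call (0.03 to 0.09), namely integrins, actin, NF-kappaB, cytokines, mitosis, BCL2, p53, and NK and cytotoxic markers. The cytokine list was called higher after the length and GC correction (median 0.15, adjusted p = 0.0438, and adjusted p = 0.68 with an estimated correlation). The calls under quantile normalization and with the sum of reads use the preset correlation.

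Markers of other blood cells were measured in the same libraries. The myeloid list was lower (median -0.65 over 5 tested members, adjusted p = 0.011, and adjusted p = 0.737 with an estimated correlation; 3 members lower adjusted over the list alone and 0 over all genes). Its median was -0.38 under quantile normalization and -0.52 with the sum of reads as library total, both still called. CTSG, the protease cathepsin G, fell from 124 to 64.3 FPKM, CST3 from 13.4 to 7.54 FPKM and AIF1 from 61.5 to 38.7 FPKM by limma-voom. The call ended after the length and GC correction, where the median was -0.52 (adjusted p = 0.068), and with every gene above 0 in the test, where the median over more members was 0.0002 (adjusted p = 0.355). NK and cytotoxic markers had a median of -0.03 over 8 members (adjusted p = 0.416), with GZMM called by the main test, and stem and progenitor markers a median of 0.13 over 6 (adjusted p = 0.551). The B cell, erythroid and epithelial lists had 3, 4 and 3 tested members, medians of -0.74, -0.07 and -0.08, and no camera test. CD79A, of the B cell list, fell from 22.9 to 13.5 FPKM by limma-voom, as did SPINK2, of the stem and progenitor list, from 24 to 12.8 FPKM, and PECAM1, of the epithelial and stromal list, from 10.9 to 7.81 FPKM. EPOR had means of 8.61 and 7.01 FPKM, and VIM of 111 and 134 FPKM.

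The libraries differed along gene length and GC content as well as by group. Across the 13172 tested genes Pearson's r of log2(FPKM + 1) was 0.986 between the controls, 0.978 between the knockdown libraries, 0.957 and 0.964 between knockdown library 1 and the controls, and 0.977 and 0.978 between knockdown library 2 and the controls. Over 10570 coding genes the difference of knockdown minus control had a Spearman correlation of 0.45 with exon length and of -0.35 with GC content. The same correlations were -0.41 and 0.17 for control 1 minus control 2, and 0.52 and -0.58 for knockdown library 1 minus 2. Genes are not independent replicates, so these are descriptions of the libraries. After the length and GC correction limma-trend called 338 genes, among them all 27. For knockdown minus control over the same coding genes, the correction left Spearman correlations of 0.10 with exon length and -0.03 with GC content.

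**Figure D4:**
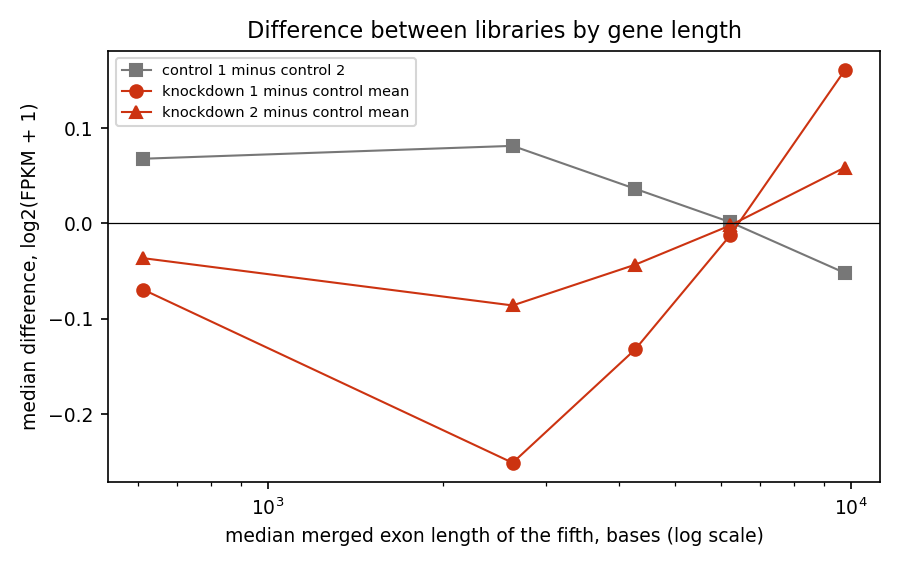
Median difference of log2(FPKM + 1) (y axis) in 5 bins of the tested genes by merged exon length (x axis, log scale), for each knockdown library minus the control mean (red) and control 1 minus control 2 (grey). In the bin of the longest genes the medians are 0.16 and 0.06 for knockdown libraries 1 and 2 and -0.05 between the controls, and in bin 2 from the shortest -0.25, -0.09 and 0.08.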

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

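The length and GC correction, the minimum of 20 recovered reads and the crossed block were chosen after seeing the data. The count of 27 genes became 45 with quantile normalization, 76 with the sum of reads as library total, 181 with a mean of at least 5 FPKM, 224 with a mean of at least 20 recovered reads and 338 with the length and GC correction. It became 1019 with limma-voom on recovered reads and 1599 with limma-voom and the correction together. By limma-trend it was 0 with every gene above 0 in the test and 0 when tested against 1.2-fold, where 3938 and 907 genes had an unadjusted p under 0.05, and it ranged from 0 to 406 when 1 library was left out. Leaving out a library leaves an arm with 1 sample, which is then assumed to vary like the other group. It was 20 and 28 with pseudocounts of 0.1 and 5. All 27 genes kept their direction in the settings that tested them, while the count at the threshold did not hold, and the cause was not tested. In all 27 both knockdown libraries lay on the same side of both controls, so leaving out a library could not change a direction. FYB1 was lower under every setting, with -1.20 on the log2 scale at a pseudocount of 5 as the smallest change. It passed the threshold except with every gene above 0 (-1.65, adjusted p = 0.264, from a range of adjusted p of 3.87e-08 to 0.264 over the alternatives), without either knockdown library and when tested against 1.2-fold, with -1.84 to -1.46 when 1 library was left out. The number of lists called was 9 to 14 under the alternatives, and 0 of 27 with an estimated correlation. The actin cytoskeleton list turned from lower and not called to higher and called with quantile normalization (median 0.12, adjusted p = 0.0151). FYB1 partners were called higher with quantile normalization and with the sum of reads as total (median 0.18 and 0.16), but not with the length and GC correction (median 0.03). Over the 142 other named genes and all alternatives, calls were gained in 484 cases and lost in 60. Many of these genes were named because limma-voom called them, so the gains under limma-voom without and with the correction (83 and 86) partly followed from that choice. The main test called 17 of the 142, and only those could lose a call. The replicate numbers share only a number: deviations of equally numbered libraries correlated at -0.21 (-0.15 after the length and GC correction), a fit with the replicate block called 781 genes and 11 lists, and a crossed replicate block called 1910 genes. The tests of DESeq2 and edgeR were planned for a file of counts and were not run, and limma-voom was the count-based test applied to the recovered reads, while the median-of-ratios scaling was not a separate alternative because it equals the authors' totals. Depth limits the genes with few reads: a gene of 1 kb at the minimum mean of 1 FPKM has 16.6 to 20.5 reads per library.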

Other observations

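The scan of 7-base words, the use of the named-gene rule on the recovered-read test and all tests of explanations below were chosen after the results had been seen.

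On recovered reads the largest falls included genes that the main test did not call. IGLL1, a component of the surrogate light chain of the pre-B cell receptor, fell from 630.0 ± 44.5 to 154 ± 43.9 FPKM (SD, n = 2 each; log2 fold change -2.06 ± 0.18, limma-voom adjusted p = 0.000536, main test adjusted p = 0.0588). TMIGD2, a costimulatory receptor of the CD28 family, fell from 11 to 4.05 FPKM, RAB20, a small GTPase, from 11.1 to 3.96 FPKM, and TRMT112, an activator of methyltransferases, from 89.2 to 33.8 FPKM. CTSW and GZMA, proteases of cytotoxic cells, fell from 40.1 to 20.3 and from 187 to 118 FPKM. Among the rises were SCG2, a secretory granule protein, from 2.62 to 8.06 FPKM, AHNAK, a large scaffold protein, from 2.89 to 7.71 FPKM, and DYNLRB1, a light chain of dynein, from 21.7 to 44.7 FPKM. PGM2L1, a glucose 1,6-bisphosphate synthase, rose from 8.69 to 17.8 FPKM, SEC31B, a coat protein of transport vesicles, from 7.55 to 14.4 FPKM, and CD52, a surface glycoprotein of lymphocytes, from 10.5 to 20.1 FPKM.

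After adjustment for gene and UTR length, GC content and expression, the 1278 genes with the word TCACAGT in the 3′ UTR were slightly lower in the knockdown libraries (log2 difference from other genes -0.07 ± 0.01 (SE), z of -9.48, the lowest of 16265 words). In pairs of libraries that share no control it was -7.77 for knockdown 1 minus control 1 and -9.83 for knockdown 2 minus control 2, the lowest in both, and -8.34 and -9.56 for the crossed pairs, with ranks 1 and 2. Adjusted means were 0.01, -0.05 and -0.10 for genes with 0, 1 and 2 or more sites, while the medians before adjustment ran the other way (-0.06, 0.0004 and 0.08), and longer coding genes were higher in the knockdown libraries (Spearman correlation of 0.45 with exon length). Without the 16 coding genes called by the main test the word ranked 2 (z = -8.72), behind CACAGTA (z = -8.80), which shares 6 of its bases. The small difference over all genes therefore rests on the adjustment. The 9 carriers among 13 fallen coding genes were counted without it, but the word was chosen by the adjusted scan, which included these genes. On recovered reads, without adjustment, 6.79%, 7.86% and 6.12% of genes with 0, 1 and 2 or more sites fell, and 2.01%, 2.77% and 2.55% rose.

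A candidate explanation for this pattern is pairing of the knockdown reagent with other transcripts through its seed. It assumes that the prefix sh in the sample titles stands for a short hairpin RNA and that both knockdown libraries carry the same one. In the 812 genes that carry the word only in the coding sequence, with a 3′ UTR free of its last 6 bases, the z was -4.73, a value that a cellular small RNA with the same seed would give as well. For control 1 minus control 2 it was -0.96. The z treats genes as independent, and no other word was scanned in coding sequences. In 3′ UTRs the lowest and highest word reached -4.56 and 8.42 for control 1 minus control 2, so a z of -4.73 is limited evidence. FYB1 carries the word, but so do 23.1% of other coding genes, so this alone is weak evidence. The median z of 627 rearrangements of the same bases without its first or last 6 was -0.63. The adjustment had already removed trends with the length and GC content of the 3′ UTR. The rearrangements could therefore hardly show base composition as the cause, and they do not decide it. A difference already present between the controls is argued against, with a z of 0.44. A change in such a cellular RNA, or a response to loss of FYB1 itself, stays open and was not tested, and the sequence of the knockdown reagent was not used here.

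The lower glycolysis, endoplasmic reticulum, nuclear respiration and ribosomal protein lists could follow the length and GC trend between libraries. Their medians lay at percentiles 0.0, 0.06, 0.01 and 0.01 of random lists matched on length, GC content and expression. The matched lists had medians of -0.09, -0.10, -0.21 and -0.25, so these traits could account for part of each fall. After the length and GC correction camera still called each at the preset correlation. With an estimated correlation, a version with little power for 2 libraries per group, it called none (adjusted p = 0.68). The correction left part of the trend (Spearman correlation of 0.10 with exon length). The percentiles and the preset correlation argue against that trend as the whole cause only if members of a list vary nearly independently. Quantile normalization, which removes a shift of all abundant genes, brought the medians of glycolysis, nuclear respiration and the endoplasmic reticulum from -0.43, -0.42 and -0.31 to -0.20, -0.19 and -0.21, so such a shift could account for part of these falls. As their whole cause it is argued against for glycolysis, the endoplasmic reticulum and nuclear respiration, which stayed called after quantile normalization (highest adjusted p = 0.00552), while for ribosomal proteins it stays open (adjusted p = 0.689), because that normalization makes the values of the most abundant genes alike in every library. Variation between libraries that moves the members of a list together cannot be told apart from an effect of the knockdown with 2 libraries per group (lowest adjusted p = 0.737 with an estimated correlation), and an effect of the lower FYB1 level remains a hypothesis beside it.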
